A study of Asparagus officinalis and Asparagus kiusianus with 18 samples.

How the data were processed

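Total RNA from stems of 2 asparagus species was sequenced by the authors: garden asparagus (*Asparagus officinalis*), listed as susceptible, and *A. kiusianus*, listed as resistant. Both species were sampled as an uninoculated control and at 24 and 48 hours after inoculation (hpi) with *Phomopsis asparagi*, the stem blight fungus, with 3 biological replicates for each group, which makes 18 libraries in 6 groups. The libraries were made with the Illumina TruSeq kit, per the labels.

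The deposited files hold 1 table per library, in which the authors added 4 columns to each line of a gene annotation. Per the file layout these are the count of alignments that overlap the line, the bases covered, the length of the line and the fraction of its bases covered, and in all 18 files the fraction equals the bases covered over the length. The count is a whole number with no normalization, and the fraction is a share between 0 and 1. The authors' processing notes list FastQC, a read quality report, cutadapt, which trims adapters, TopHat2, a spliced aligner, and bedtools, which counts alignments over intervals. Their versions, their settings, the genome build and whether strand was used are not given in the sources used here. The 514331 lines per file, 292566 of them exons and 221765 coding segments, were identical in all 18 files. The gene symbols of all 32237 annotated genes were found in the RefSeq table for the Aspof.V1 assembly, and start and end matched for 32231 of them.

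A gene's count was the sum over its distinct exon intervals. A read that spans a junction is thus counted once for each exon it touches, and overlapping exons of isoforms count a read more than once. Counts of overlapping or near-identical genes cannot be separated in these files, so values of single genes are uncertain where copies exist. Neither the files nor the reference names gene products. For this reason the 37 gene lists fixed in advance, on defence, hormone, cell wall, photosynthesis and tissue markers, could not be matched to genes, and neither those lists nor their list tests were run. Genes are instead described by symbol, position and annotated type (protein-coding, long non-coding RNA or pseudogene).

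Tests used edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, on 1 model of the 18 libraries and 6 groups. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and each comparison used the quasi-likelihood F test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment over the 24945 genes kept and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. Levels are CPM values on TMM-scaled library sizes, with the SD over 3 libraries. Of 3 libraries against 3, an exact permutation test of a single gene cannot give a p under 0.1, so single genes rest on the model's adjusted p. The 9 comparisons were each time against control in each species, 48 against 24 hpi in each species, the 2 sets of controls against each other, and the difference between the species' responses at each time. Shares of annotated types among changed genes were compared with Fisher's exact test, adjusted over 27 tests, and overlaps of gene sets with Fisher's exact test over 8 tests. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 served for the counts and the plots.

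The comparisons, tests, a first set of processing alternatives and the rule for named genes were fixed before the data were examined. The rule names at most 2 genes that rose and 2 that fell per comparison: those with the largest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the replicates, which chance gives for 10% of genes at 3 against 3. Where none passed the threshold, the 2 smallest unadjusted p in each direction were taken instead. Any other gene named below was chosen after its values were seen. Where a fold is given for a gene with no count in a group, it is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in the lower group, the ratio of the counts is given with its 95% interval (exact Clopper-Pearson, from the split of the counts). Genes with nearly all their counts in *A. kiusianus* control library 1 are the exception and have the fitted log2 fold change. Floors and intervals cover counting error only, and the reads carry no molecular identifiers. They treat counts as independent and leave out the spread between replicates. Where a read counts on several exons they are too narrow even for counting error.

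The summed counts ranged from 26084356 to 35489843 per library, apart from *A. kiusianus* control library 1 with 96010362. No count in a library leaves room for 0.0816 to 0.138 CPM, at 3 counts on the TMM-scaled size. Tested on simulated data in groups of 3 with the spread of the real libraries, the test recovered 79% of genes changed 4-fold and 19% of those changed 2-fold at 24 hpi in *A. officinalis*, and 73% and 18% in *A. kiusianus*. For the difference between the responses the recovery was 43% at 4-fold and 0% at 2-fold. Changes were put only in genes with a control mean of at least 5 CPM over both species. Recovery among genes of lower level was not measured. Wrong calls numbered 2, 5 and 0 in these 3 runs.

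That first set of alternatives was coding segments in place of exons, the size factors of DESeq2 in edgeR, DESeq2 1.42.0 itself, no low-count filter, at least 1 CPM in 3 libraries, a minimum log2 change of 1, a fit to the libraries of the species or groups compared only, the replicate number as a block, and leaving out each of the 18 libraries. Alternatives added after the data were seen were subtraction of the smallest exon count of neighbouring genes, the largest count per cluster of overlapping exons, subtraction of an *A. officinalis* share from the *A. kiusianus* controls, and leaving out *A. kiusianus* control libraries 1 and 2, alone or with *A. officinalis* 24 hpi library 3. No block was used in the reported values, as set beforehand, since no label states a shared batch behind a replicate number. Within a species, residuals of libraries with the same number had a mean correlation of -0.04 (-0.366 to 0.396). With different numbers it was 0.018 (-0.512 to 0.388). These wide ranges do not exclude that some numbers pair samples. The coding segment counts and the fraction covered served only for checks. No library was left out of the reported values.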

Results

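Gene activity in stems was measured by RNA sequencing in garden asparagus (*Asparagus officinalis*) and its wild relative *A. kiusianus*, without inoculation and 24 and 48 h after inoculation (hpi) with the stem blight fungus *Phomopsis asparagi*. Each of the 6 groups held 3 libraries. The controls were uninoculated and have no sampling time in the labels, and the same controls served for 24 and 48 hpi. Effects of handling or of time are therefore not separated from those of the fungus in any comparison with control. Summed exon counts ranged from 26084356 to 35489843 per library, except in *A. kiusianus* control library 1, which held 96010362. The 10 genes with the most counts took 31.1% of that library and 4.3 to 6.39% of each other library. Between 24973 and 26089 of the 32237 annotated genes had a count in each library, and 24945 were tested. All values were read against the *A. officinalis* annotation. Among exons with at least 10 counts, 78.15 to 79.23% were covered over their full length in the *A. officinalis* libraries and 70.67 to 74.74% in those of *A. kiusianus*, a difference that was not tested.

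The 2 species were parted by the first principal component of log2 CPM, which held 59.4% of the variance. Along the second, with 12.8%, the *A. officinalis* controls lay at 61.3 to 124.4, the 48 hpi libraries at -70.3 to -51.5 and 24 hpi libraries 1 and 2 at -105.2 and -115.4. *A. officinalis* 24 hpi library 3 lay among the controls at 77.6. Its mean correlation over genes was 0.958 with the controls and 0.884 with the other libraries of its group. The 6 inoculated *A. kiusianus* libraries lay close together on the first component, at -168.1 to -161.9, and the 3 controls lay apart from them and from each other, at -124.6, -47 and -90.4.

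**Figure D1:**
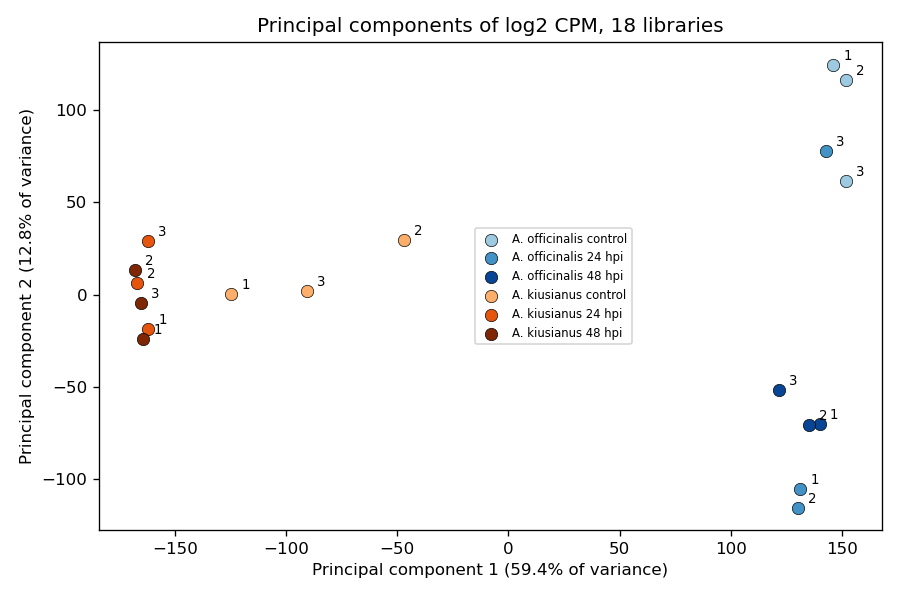
First and second principal components of log2 CPM (% of variance on each axis) for the 18 libraries, 1 point per library, coloured by species and time, with the replicate number beside it. *A. officinalis* 24 hpi library 3 lies at 77.6 on the second component, between its controls, and the *A. kiusianus* controls are spread from -124.6 to -47 on the first.

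A set of 63 genes, chosen after the data were seen, had at least 10 CPM in every *A. officinalis* library and at most 0.2 CPM in each of the 6 inoculated *A. kiusianus* libraries. The choice did not use the *A. kiusianus* controls. In these the genes stood at a median of 2.07%, 17.8% and 5.5% of their *A. officinalis* mean, in libraries 1, 2 and 3. A further 221 genes, with a lowest *A. officinalis* level of 2 to 10 CPM, stood at 1.86%, 20% and 7.39%. Of the 63 genes 33 were long non-coding RNAs and 26 protein-coding.

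**Figure D2:**
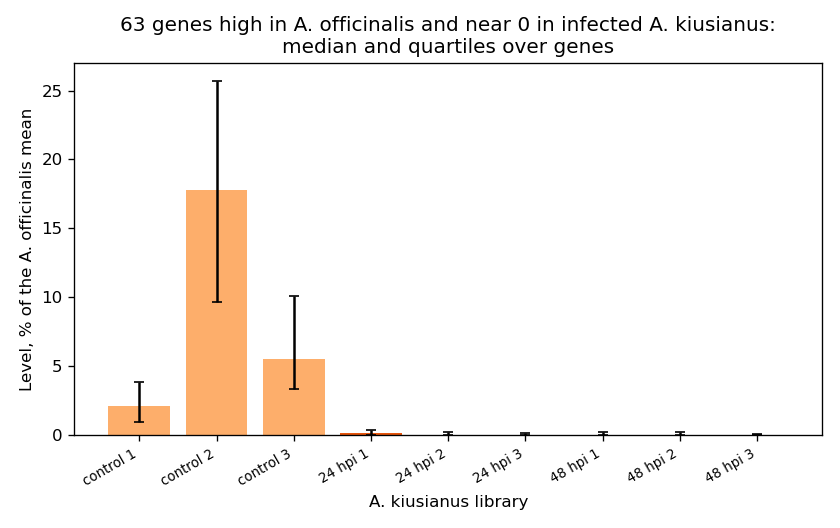
Level of the 63 genes in each *A. kiusianus* library, in % of their *A. officinalis* mean, with bars for the median over genes and whiskers for the quartiles. The medians were 2.07%, 17.8% and 5.5% in the 3 controls and at most 0.14% in the 6 inoculated libraries.

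Neighbouring genes in a stretch of chromosome 8 took 25.9% of the counts of *A. kiusianus* control library 1 and at most 0.127% of any other library. No interval is given for the shares of this library, since counts of the same alignment on several exons are not independent. All 17 protein-coding genes between 96281998 and 96668407 on chromosome 8, among them LOC109821566, had a smallest exon count within 1% of 255783 in that library. Subtracting from each gene the smallest exon count of its nearest neighbours removed 51.4% of this library's counts and 3.28 to 4.91% of the others. The same subtraction removed 99.9% of the counts of LOC109851211, 99.2% of LOC109820463 and 99.9% of LOC109821566, and with it 2361 genes were called at 24 hpi in *A. kiusianus*, 451 of them higher.

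**Figure D3:**
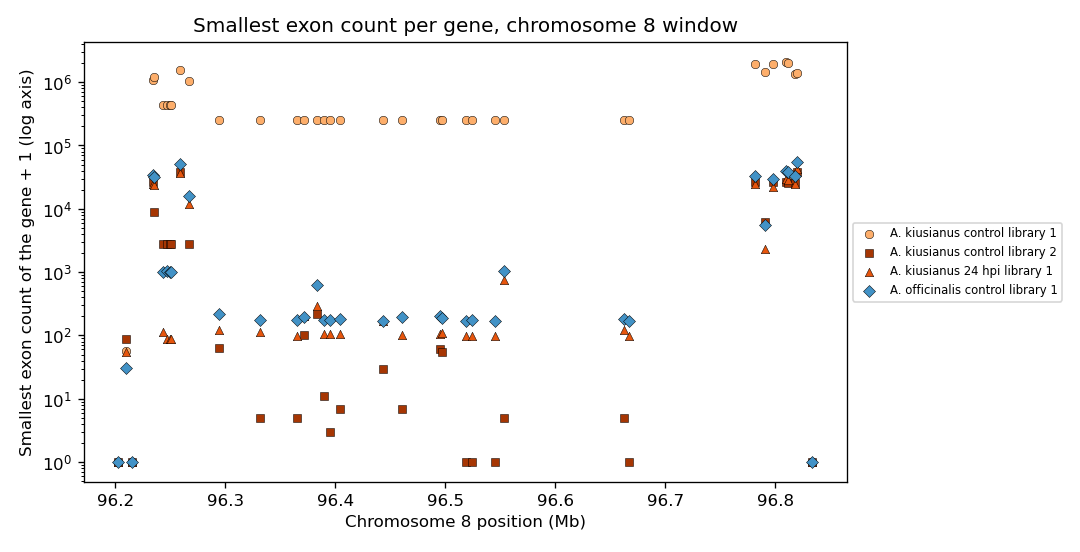
Smallest exon count of each gene plus 1 (log axis) along a stretch of chromosome 8 (position in Mb) in 4 libraries. In *A. kiusianus* control library 1 the 17 protein-coding genes from 96281998 to 96668407 lie at 1 level, near 255783 counts.

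In the susceptible species 2531 genes differed from the controls at 24 hpi, 10.1% of those tested, of which 1338 (52.9%) were higher and 1193 lower than in uninoculated stems. LOC109830209, a protein-coding gene on chromosome 2 (10164113 to 10174141), fell from 11 ± 0.702 CPM (SD, n = 3) to 0.0477 ± 0.0605 CPM, a log2 fold change of -7.69 (SE 1.1, adjusted p = 0.000757). LOC109829659, also on chromosome 2 (3111133 to 3114716), fell from 11.6 ± 4.53 to 0.0869 ± 0.15 CPM, a log2 fold change of -6.97 (SE 1.3, adjusted p = 0.00434). LOC109835904 on chromosome 4 (37599718 to 37600902) had no count in the controls and 7.68 ± 9.68 CPM at 24 hpi, at least 258-fold higher (adjusted p = 0.0115). LOC109846831 on chromosome 7 (23911220 to 23915616) also had no count in the controls and reached 6.06 ± 7.35 CPM, at least 204-fold higher (adjusted p = 0.0142). Both rises came from 24 hpi libraries 1 and 2, since library 3 held 1 count of LOC109835904 and 3 of LOC109846831. Long non-coding RNAs were called less often than protein-coding genes: 109 of 2622 (4.2%), against 10.8% (odds ratio 0.357, Fisher's exact test, adjusted p = 2.5e-31, genes not being independent). The test was not matched on level, so lower counts may play a part. In control library 1 the 3735 annotated long non-coding RNAs took 4.21% of the counts and the 26460 protein-coding genes 89.9%.

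The size of this response depended on single libraries. It came to 6779 genes without 24 hpi library 3, the one near the controls, and to 1200 without 24 hpi library 1, 1041 without library 2, 990 without control library 1 and 897 without control library 2. The share of genes that were higher depended on the fit: it was 172 of 738 (23.3%) when only the 9 *A. officinalis* libraries were fitted and 378 of 1227 (30.8%) with the replicate number as a block. The rise of LOC109846831 was not past the threshold without control library 1 (adjusted p = 0.054) or 2 (adjusted p = 0.0588), nor in the fit to the 9 *A. officinalis* libraries (0.0635), where that of LOC109835904 was lost as well (0.08).

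By 48 hpi the response in *A. officinalis* covered 4856 genes, 19.5% of those tested, with 2276 (46.9%) higher and 2580 lower than in the controls. LOC109832149 on chromosome 3 (23529451 to 23530113) rose from 0.357 ± 0.424 to 74.5 ± 8.4 CPM, a log2 fold change of 7.71 (SE 1.1, adjusted p = 0.000362). Its level at 24 hpi was 8.15 ± 8.68 CPM, and in the *A. kiusianus* groups it averaged at most 0.597 CPM. LOC109829412 on chromosome 2 (12044187 to 12045754) rose from 2 counts in the 3 controls to 5.72 ± 1.81 CPM, a ratio of 286 with a 95% interval of 78.9 to 2370 (adjusted p = 0.00871). LOC109841956 on chromosome 1 (131673899 to 131676084) fell from 14.2 ± 6.43 CPM to 1 count in 3 libraries, a ratio of 1330 with a 95% interval of 238 to 52500 (adjusted p = 0.000382). It was also lower in inoculated *A. kiusianus*, at 1.24 ± 0.867 CPM in the controls, 0.0376 ± 0.0326 CPM at 24 hpi (adjusted p = 0.0164) and 2 counts in 3 libraries at 48 hpi, a ratio of 66.7 with a 95% interval of 18.1 to 557 (adjusted p = 0.0113). Those calls in *A. kiusianus* were lost with the *A. officinalis* share subtracted, where the log2 fold changes shrank from -4.91 to -1.80 (adjusted p = 0.502) and from -5.67 to -2.57 (adjusted p = 0.365), at 24 hpi without control library 2 (0.0605) or 24 hpi library 2 (0.0759) or 3 (0.0583), and at 48 hpi without 48 hpi library 3 (0.0535). LOC109826900 on chromosome 10 (71058504 to 71058848) fell from 12.6 ± 1.09 CPM to no count, at least 389-fold lower (adjusted p = 0.000623). Long non-coding RNAs were again called less often than protein-coding genes, 218 of 2622 (8.3%) against 20.9% (odds ratio 0.343, Fisher's exact test, adjusted p = 1.66e-61, genes not being independent or matched on level). The number of genes called at 48 hpi fell to 2577 without control library 1, 2481 without control library 2, 2930 without 48 hpi library 1 and 2671 without 48 hpi library 2. Without 24 hpi library 3 it rose to 6538, where the number at 24 hpi was 6779. That the response was larger at 48 than at 24 hpi thus depended on this library.

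The 24 and 48 hpi responses of *A. officinalis* overlapped. Of the genes higher at 24 hpi 941 were also higher at 48 hpi, where independent sets would share 122.1, and of those lower 1003 were lower at both times, against 123.4. Genes with opposite calls numbered 3 and 1. Both responses were measured against the same 3 controls. In simulated libraries of this species with no change this alone gave a mean correlation of log2 fold changes across genes of 0.493, against 0.756 here. It gave 0 genes called at both times, but with no change few calls can arise at all. The 0 therefore does not show how far shared controls raise the overlap. The simulated genes varied independently, so a shift of many genes together in 1 control library was not included.

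Between 24 and 48 hpi, 38 genes differed in *A. officinalis*, 16 of them higher at 48 hpi and 22 lower. LOC109845019 on chromosome 6 (15946816 to 16005213) rose from 0.501 ± 0.163 to 8.19 ± 1.63 CPM (log2 fold change 4.02, SE 0.43, adjusted p = 0.0014), and its control level was 1.47 ± 0.33 CPM. LOC109843281 on chromosome 5 (31119815 to 31122066) rose from 1.39 ± 0.899 to 9.52 ± 2.35 CPM (log2 fold change 2.76, SE 0.51, adjusted p = 0.0486). LOC109843984 on chromosome 1 (115793530 to 115796464) fell from 15.6 ± 5.78 to 1.04 ± 0.482 CPM (log2 fold change -3.9, SE 0.47, adjusted p = 0.00221), below its control level of 5.71 ± 1.14 CPM. LOC109832115 on chromosome 3 (18196018 to 18198355) fell from 5.87 ± 2.79 to 0.121 ± 0.116 CPM (log2 fold change -5.56, SE 0.84, adjusted p = 0.0153).

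That count of 38 was set by single libraries. It rose to 713 without 24 hpi library 3, 559 without 24 hpi library 1 and 59 without control library 3. It fell to 22 and 23 without control libraries 1 and 2, 10 without 24 hpi library 2, 8, 10 and 20 without 48 hpi libraries 1, 2 and 3, and 19 without *A. kiusianus* control library 3, 24 hpi library 2 or 48 hpi library 1. It was 23 without *A. kiusianus* 24 hpi library 1 and 21 without its 48 hpi library 3. No gene passed when only the 9 *A. officinalis* libraries were fitted, and DESeq2 called 677. The fall of LOC109832115 was not past the threshold without 24 hpi library 2 (adjusted p = 0.0523), 48 hpi library 1 (0.0607) or 48 hpi library 2 (0.128). The rise of LOC109843281 was lost in 14 of the 18 fits that left out 1 library, namely without *A. officinalis* control library 1 (0.0653), 24 hpi library 2 (0.112) or 48 hpi libraries 1 to 3 (0.106, 0.222 and 0.104), and without *A. kiusianus* control libraries 1 to 3 (0.0537, 0.0508 and 0.0763), 24 hpi libraries 1 to 3 (0.0726, 0.0838 and 0.0716) or 48 hpi libraries 1 to 3 (0.0756, 0.0573 and 0.0701).

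In the resistant species 2503 genes had changed by 24 hpi, 10% of those tested, and the falls outnumbered the rises: 491 (19.6%) were higher and 2012 lower than in the controls. LOC109826346, a long non-coding RNA on chromosome 10 (55986745 to 55990526), rose from 0.15 ± 0.129 to 5.67 ± 3.82 CPM (log2 fold change 5.16, SE 1.17, adjusted p = 0.0109). LOC109837305 on chromosome 4 (42518694 to 42536441) rose from no count to 7.71 ± 7.89 CPM, at least 227-fold higher (adjusted p = 0.0407). LOC109851211 and LOC109820463, long non-coding RNAs on chromosome 8 (103055339 to 103062453 and 103016485 to 103017445), met the rule for the largest falls through control library 1 alone. The 3 controls held 245176, 16 and 2 counts of LOC109851211 and 61295, 18 and 5 of LOC109820463, and without control library 1 their log2 fold changes shrank from -18.1 to -4.29 (adjusted p = 0.0622) and from -15.32 to -3.87 (adjusted p = 0.0046). Long non-coding RNAs took a larger part here than protein-coding genes, with 45 higher and 493 lower of 2622 (20.5%) against 8.6% (odds ratio 2.74, Fisher's exact test, adjusted p = 2.34e-66, genes not being independent). Of the 63 genes that set the controls apart, 33 are of this type. With the *A. officinalis* share subtracted, 89 were higher and 273 lower (13.8%, against 7.8% of protein-coding genes). Without control libraries 1 and 2 the shares were 11.5% and 3.1%, and without the 63 and the 221 genes they were 16.4% and 8.2%.

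With the *A. officinalis* share estimated from the 63 genes subtracted from each control, 2133 genes were called, 681 (31.9%) of them higher, and with only the 9 *A. kiusianus* libraries fitted 1809, of which 695 (38.4%) were higher. The count was 1596 without control library 2, 1290 without 24 hpi library 2, 1411 without 24 hpi library 3 and 1048 without control libraries 1 and 2 together, where 110 (10.5%) were higher. The call of LOC109837305 was lost without any 1 of the controls (adjusted p = 0.0796, 0.124 and 0.0984 for libraries 1 to 3), 24 hpi library 2 (0.0735) or 3 (0.106), *A. officinalis* control library 2 (0.0557) and its 24 hpi libraries 1 (0.05) and 2 (0.0506). The call of LOC109826346 was lost without control library 2 (0.0509), and that of LOC109851211 also without 24 hpi library 3 (0.0519).

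By 48 hpi 2803 genes had changed in *A. kiusianus*, 11.2% of those tested, with 709 (25.3%) higher and 2094 lower. LOC109848328 on chromosome 7 (135948234 to 135966759) rose from 1.78 ± 0.216 to 42.4 ± 14.1 CPM (log2 fold change 4.58, SE 0.4, adjusted p = 1.34e-05) and stood at 27.1 ± 13.8 CPM at 24 hpi. In *A. officinalis* the same gene fell from 56.3 ± 21.2 to 18.9 ± 4.18 CPM (adjusted p = 0.00592, and 0.108 with the *A. officinalis* share subtracted from the *A. kiusianus* controls). LOC109823679 on chromosome 9 (7715994 to 7721890) rose from 2.49 ± 0.822 to 72.8 ± 33.9 CPM (log2 fold change 4.87, SE 1.06, adjusted p = 0.0081), without passing the threshold when control libraries 1 and 2 were left out together (adjusted p = 0.169). The genes named for the largest falls, LOC109820463 and LOC109821566 (chromosome 8, 96494432 to 96495415), again had nearly all their control counts in library 1, with 255784, 60 and 12 counts of LOC109821566. Without it the log2 fold change of LOC109820463 shrank from -16.03 to -4.59 (adjusted p = 0.00248) and that of LOC109821566 from -14.64 to -2.76 (adjusted p = 0.248), and the call of LOC109821566 was lost as well without 48 hpi library 1 (0.0612) or 3 (0.0582). Long non-coding RNAs were over-represented here too, with 63 higher and 477 lower, 20.6% against 10% (odds ratio 2.34, Fisher's exact test, adjusted p = 4.67e-50, genes not being independent). With the *A. officinalis* share subtracted 113 were higher and 268 lower (14.5%, against 9.2%). Without control libraries 1 and 2 the shares were 11.1% and 3.5%, and without the 63 and the 221 genes 16.5% and 9.6%. The count was 1763 without control library 2, 1510 without 48 hpi library 1, 1668 without 48 hpi library 3 and 1139 without control libraries 1 and 2 together, where 167 (14.7%) were higher. With the *A. officinalis* share subtracted, 942 (38%) of 2482 genes were higher, and with only the *A. kiusianus* libraries fitted 929 (40.7%) of 2282.

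**Figure D4:**
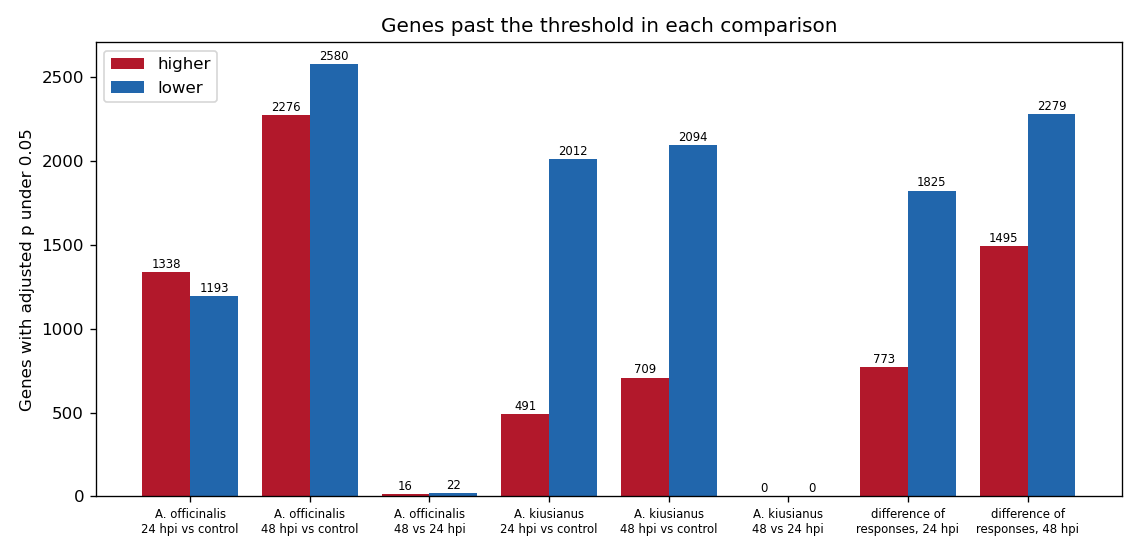
Number of genes with an adjusted p under 0.05 (vertical axis) that were higher or lower in the infection and time comparisons of each species and in the differences between the species' responses. Falls outnumbered rises in *A. kiusianus*, 2012 to 491 at 24 hpi and 2094 to 709 at 48 hpi.

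The 2 times shared most of their calls in *A. kiusianus*: 333 genes were higher at both, where independent sets would share 14, and 1466 were lower at both, against 168.9. No gene was called in opposite directions, and the correlation of log2 fold changes across genes was 0.887, against a mean of 0.503 that shared controls alone gave in simulated libraries. The simulated libraries were all drawn from the control means, so transcripts that only the controls hold were not simulated. Such transcripts would add shared falls and raise the correlation. LOC109834150 on chromosome 3 (53791286 to 53792939), chosen after its values were seen, had 196, 2194 and 624 counts in the controls, a mean of 30 ± 27.1 CPM, and no count at either time after inoculation, at least 1050-fold lower at 24 hpi and 977-fold at 48 hpi (adjusted p = 7.44e-05 and 7.98e-05). It averaged 103 to 149 CPM in the *A. officinalis* groups. LOC109831657 on chromosome 2 (76160020 to 76179269), chosen in the same way, had 15.4 ± 4.94 CPM in the controls, 1 count in the 3 libraries at 24 hpi and none at 48 hpi, at least 500-fold lower (adjusted p = 4.14e-07), while the *A. officinalis* groups averaged 17.3 to 19.4 CPM. Both genes belong to the 63 typical of *A. officinalis*, with LOC109834150 at 9, 60.6 and 20.4 CPM in controls 1 to 3. LOC109831657, at 16.4, 10 and 19.7 CPM, stood far above the median share of the set in each control.

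Between 24 and 48 hpi no gene of *A. kiusianus* passed the threshold in edgeR, where 1719 had an unadjusted p under 0.05, and DESeq2 called 170. The smallest p values belonged to LOC109835733 on chromosome 3 (110 ± 30.2 to 33.3 ± 13.7 CPM, log2 fold change -1.72, adjusted p = 0.0553), LOC109825641 on chromosome 10 (25.8 ± 10.5 to 1.59 ± 1.07 CPM, -4.00, adjusted p = 0.0553), LOC109832559 on chromosome 3 (3.6 ± 1.51 to 23.2 ± 13.6 CPM, 2.69, adjusted p = 0.0554) and LOC109836332 on chromosome 4 (1.28 ± 0.275 to 6.18 ± 2.2 CPM, 2.27, adjusted p = 0.0554). Leaving out 1 library brought these 4 genes past the threshold in 4 cases: without *A. kiusianus* control library 1 (10 genes in all, adjusted p of the 4 from 0.0325 to 0.046), control library 2 (11 genes, 0.0283 to 0.0366), 48 hpi library 2 (39 genes, 0.00325 to 0.0162) and *A. officinalis* 24 hpi library 3 (7 genes, 0.00904 to 0.0451). With the neighbour subtraction the log2 fold change of LOC109825641 was -0.73 (adjusted p = 0.952) and the other 3 genes had an adjusted p of 0.0847. In the fit to the 9 *A. kiusianus* libraries the adjusted p was 0.112 for LOC109825641 and 0.142 for the other 3. All 4 passed in DESeq2, with coding segments (adjusted p of 0.0428 to 0.0494) and with no low-count filter (0.0499). With the replicate number as a block none did (0.0711 to 0.141), and without *A. kiusianus* control libraries 1 and 2 together 3 did, all but LOC109832559 (0.0587). On simulated libraries in groups of 3, the test recovered 73% of genes changed 4-fold and 18% of those changed 2-fold between *A. kiusianus* groups, 24 hpi against control. These were genes with a control mean of at least 5 CPM over both species, and genes of lower level were not measured.

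Without inoculation the 2 species differed in 11595 genes, 46.5% of those tested, with 5819 higher in *A. kiusianus* and 5776 lower. Reads of both species were read against the annotation of *A. officinalis*. Differences in sequence or gene content may therefore enter these counts and folds beside differences in expression. LOC109839566 on chromosome 4 (140137755 to 140139524) had 67.2 ± 7.63 CPM in the *A. officinalis* controls and no count in those of *A. kiusianus*, at least 1980-fold lower (adjusted p = 1.04e-07). It averaged at most 0.279 CPM in inoculated *A. kiusianus*. LOC109846804 on chromosome 1 (4741956 to 4744821) had 30.1 ± 18.2 CPM in *A. officinalis* and no count in any of the 9 *A. kiusianus* libraries, at least 890-fold lower in the controls (adjusted p = 0.000125). The genes named as higher, LOC109821628 (103046351 to 103052486) and LOC109821627 (103044693 to 103045861), are neighbours on chromosome 8 and had 91949 and 183902 counts in *A. kiusianus* control library 1 against at most 102 in the others. Without that library their log2 fold changes shrank from 16.64 to 5.61 (adjusted p = 0.00192) and from 15.69 to 5.45 (adjusted p = 0.000295). Of the long non-coding RNAs 446 were higher and 968 lower in *A. kiusianus*, 53.9% against 45.4% of protein-coding genes (odds ratio 1.41, Fisher's exact test, adjusted p = 9.9e-16, genes not being independent), where reads of *A. kiusianus* were placed on the annotation of the other species. Without *A. kiusianus* control libraries 1 and 2 together 7547 genes differed, and no single library moved the count by more than 1.5-fold.

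The responses of the 2 species overlapped by more than independent sets would, and some genes had opposite calls. At 24 hpi 39 genes were higher in both, against 26.3 for independent sets (odds ratio 1.54, Fisher's exact test, adjusted p = 0.0147), and 164 were lower in both, against 96.2 (odds ratio 1.89, adjusted p = 1.48e-11). At 48 hpi 104 were higher in both, against 64.7 (odds ratio 1.75, adjusted p = 1.56e-06), and 267 lower, against 216.6 (odds ratio 1.3, adjusted p = 0.000269). Genes higher in *A. officinalis* and lower in *A. kiusianus* numbered 49 at 24 hpi and 98 at 48 hpi, and 28 and 57 had the reverse calls. For these opposite calls the number that independent sets would share was not computed, so the counts do not show that opposite calls stand out. The log2 fold changes of the species correlated across genes at 0.042 and 0.086, genes not being independent replicates. In all 4 comparisons with control 24 genes were higher and 99 lower. The shared falls may include genes that stood high in the *A. kiusianus* controls only through the transcripts typical of *A. officinalis*, which these numbers do not separate. Of the 99, LOC109841956 lost its calls in *A. kiusianus* with the *A. officinalis* share subtracted, and LOC109838821 kept them. LOC109840277 on chromosome 5 (96397636 to 96399268), chosen after its values were seen, rose in *A. officinalis* from 23.7 ± 6.36 to 123 ± 71.4 and 104 ± 9.29 CPM at the 2 times, and in *A. kiusianus* from 32.5 ± 12.1 to 102 ± 30.1 and 135 ± 30.5 CPM. Its rise at 24 hpi in *A. kiusianus* (adjusted p = 0.0208) was lost without control library 2 (0.102) or 3 (0.0553) and without 24 hpi library 1 (0.0795) or 2 (0.0525). LOC109838821 on chromosome 4 (63921675 to 63922602), chosen in the same way, fell from 16.6 ± 3.46 to 0.445 ± 0.0886 and 0.24 ± 0.139 CPM in *A. officinalis* and from 9.62 ± 9.26 CPM to no count in *A. kiusianus*.

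Tested directly, the response differed between the species in 2598 genes at 24 hpi and 3774 at 48 hpi. At 24 hpi the response of *A. kiusianus* was the higher one in 773 (29.8%) and the lower one in 1825, and at 48 hpi in 1495 (39.6%) and 2279. With the *A. officinalis* share subtracted the higher ones were 971 of 2415 (40.2%) and 1851 of 3824 (48.4%), and without *A. kiusianus* control libraries 1 and 2 they were 23% of 1211 and 30.1% of 1697. LOC109830209 fell in *A. officinalis* at 24 hpi, as given above, and stood at 1.91 ± 1.11 and 1.61 ± 1.23 CPM in *A. kiusianus* before and after, a difference of responses of 7.44 on the log2 scale (SE 1.32, adjusted p = 0.00345). At 48 hpi it stood at 0.235 ± 0.183 CPM in *A. kiusianus* (adjusted p against control 0.0382), and the difference of 3.39 was not past the threshold (adjusted p = 0.0809). LOC109842870, a long non-coding RNA on chromosome 1 (75718559 to 75719833), rose in *A. officinalis* from 4 counts in the controls to 5.42 ± 2.52 CPM at 48 hpi and fell in *A. kiusianus* from 2.3 ± 1.57 CPM to no count (adjusted p of the difference 0.00188). Genes that fell in *A. officinalis* and rose in *A. kiusianus* at both times numbered 14, and 21 did the reverse. The numbers that independent sets would give were not computed for these either. Among the 14, LOC109848328 differed by 5.45 at 24 hpi (SE 0.52, adjusted p = 5.26e-05) and 6.15 at 48 hpi (SE 0.52, adjusted p = 1.22e-05). Its fall in *A. officinalis* at 24 hpi (adjusted p = 0.0133) was lost without 24 hpi library 1 (0.0535) or 2 (0.0581) and with the share subtracted (0.167). LOC109824603 on chromosome 9 (8034441 to 8043897), chosen after its values were seen, fell from 155 ± 11.6 to 41 ± 2.23 CPM at 48 hpi in *A. officinalis* and rose from 37.4 ± 21.7 to 311 ± 95.6 CPM in *A. kiusianus* (difference 4.97, SE 0.51, adjusted p = 6.1e-05). Among the 21, LOC109828931 on chromosome 1 (109450528 to 109452466), also chosen after its values were seen, rose from 1.18 ± 0.539 to 16.3 ± 3.66 CPM in *A. officinalis* and fell from 27.9 ± 8.38 to 0.757 ± 0.307 CPM in *A. kiusianus* (difference -8.98, SE 1.15, adjusted p = 0.000291).

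**Figure D5:**
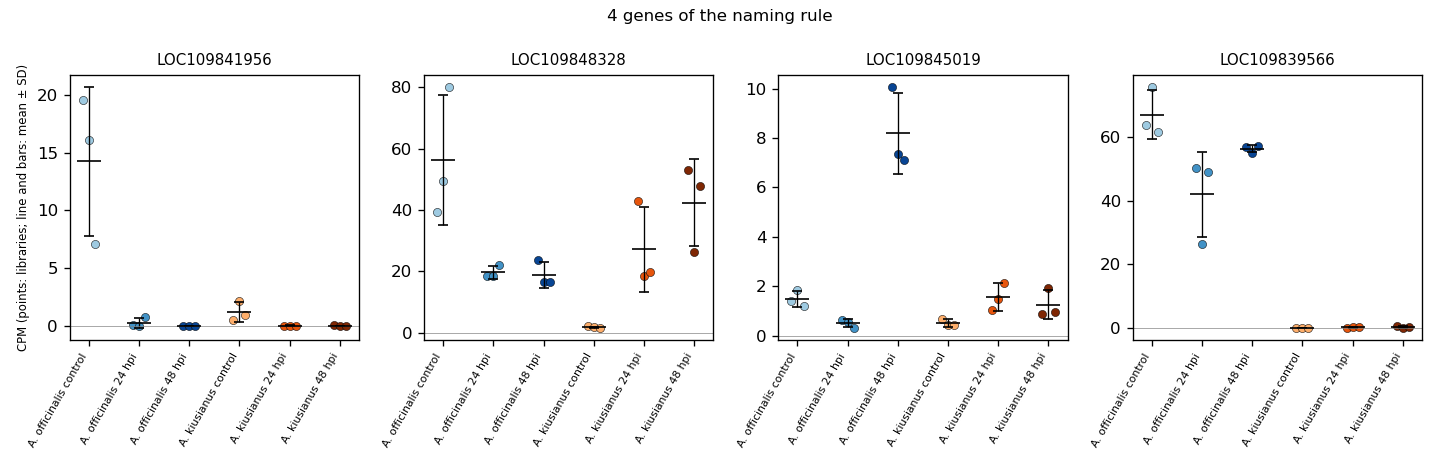
Level in CPM of 4 named genes in each library (points), with the mean and SD of each group of 3 (lines and bars). LOC109848328 fell in *A. officinalis* and rose in *A. kiusianus*. LOC109841956 fell in both species, in *A. kiusianus* from a lower level and with its calls lost when the *A. officinalis* share was subtracted. LOC109845019 was highest in *A. officinalis* at 48 hpi, and LOC109839566 had no count in the *A. kiusianus* controls.

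The other genes named for the difference rested on few libraries. LOC109837305 had no count in the *A. kiusianus* controls and 7.71 ± 7.89 CPM at 24 hpi, against 0.673 ± 0.597 and 0.0597 ± 0.0555 CPM in *A. officinalis* (adjusted p = 0.0322). That call was lost without *A. officinalis* control library 1 (0.0729) or 2 (0.0591), its 24 hpi library 1 (0.0621) or 2 (0.073), *A. kiusianus* control library 2 (0.0582) or 3 (0.0606), or its 24 hpi library 2 (0.0538) or 3 (0.07). LOC109829694 on chromosome 2 (82298399 to 82300263) had 372, 351 and 0 counts in the *A. officinalis* controls and none at 48 hpi, against 0.278 ± 0.146 and 1.16 ± 1.91 CPM in *A. kiusianus* (adjusted p = 0.0351). It was lost without *A. officinalis* control library 1 (0.0686) or 2 (0.0671), any of its 48 hpi libraries (0.073, 0.0725 and 0.0642), any *A. kiusianus* control (0.0643, 0.0569 and 0.0717) or 48 hpi library 1 (0.198). LOC109849020 on chromosome 7 (89270875 to 89272193) stood at 55.2 ± 47.9 and 0.495 ± 0.716 CPM in *A. officinalis* before and 48 h after inoculation, and at 0.282 ± 0.276 and 5.44 ± 6.17 CPM in *A. kiusianus* (adjusted p of the difference 0.0389). Its *A. officinalis* controls held 92.7, 71.5 and 1.25 CPM and the 24 hpi libraries 0, 0 and 100.8 CPM. Control 3 and 24 hpi library 3 thus each resembled the other group. The call of LOC109849020 was lost without *A. officinalis* control library 1 (0.074) or 2 (0.0697), any of its 48 hpi libraries (0.0928, 0.0947 and 0.0517), any *A. kiusianus* control (0.066, 0.0812 and 0.0818), 24 hpi library 2 (0.0503) or 48 hpi library 2 (0.0827) or 3 (0.0541).

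LOC109851211 and LOC109820463, with nearly all their counts in *A. kiusianus* control library 1, had the lowest differences at 24 hpi (adjusted p = 0.0119 and 0.0136), and LOC109851211 again at 48 hpi (adjusted p = 0.0104). The call of LOC109851211 was lost at 24 hpi without *A. kiusianus* 24 hpi library 3 (0.0501) and at 48 hpi without control library 1 (0.0921). The number of genes with a difference at 24 hpi was 6456 without *A. officinalis* 24 hpi library 3, 1702 without its 24 hpi library 2, 1404 and 1323 without its control libraries 1 and 2, and 1362 and 1425 without *A. kiusianus* 24 hpi libraries 2 and 3. At 48 hpi it was 2402 and 2252 without *A. officinalis* control libraries 1 and 2, and 2477 and 2444 without its 48 hpi libraries 1 and 2. Without *A. kiusianus* control libraries 1 and 2 together the numbers at the 2 times were 1211 and 1697.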

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

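The tests on the repeated count along chromosome 8 and on the position of *A. officinalis* 24 hpi library 3, and those of control 2 against control 3 for shut-off genes and of abundant genes with no count in a control, were chosen only after the results were seen, with their limits. Each result in the next 2 paragraphs was singled out because the response to inoculation differed between the species in a direct test of that difference.

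The response differed in 2598 genes at 24 hpi and in 3774 at 48 hpi. At 24 hpi, 2 of 40 drawn splits of the samples gave as many genes, with a highest other split of 4351, so chance was not excluded. That split exchanged *A. officinalis* control 3 and 24 hpi library 3, which points to a structure of the samples. At 48 hpi only the real split of the 40 gave as many, with 1529 in the highest other, where only *A. kiusianus* libraries were exchanged. The splits mix control and inoculated libraries within a species, so they break up the responses themselves. Their counts therefore cannot decide whether the species' responses differ by chance. The splits of the other 7 comparisons numbered 10 each, too few for a share under 0.05. In *A. officinalis* at 24 hpi 2 splits gave as many genes as the real 2531, with 3410 in the highest other, again the exchange of control 3 and 24 hpi library 3. At 48 hpi the real 4856 was reached by 1 split, the real one, with 2 genes in the highest other. In *A. kiusianus* 1 split reached the real 2503 at 24 hpi (highest other 4) and 1 the real 2803 at 48 hpi (highest other 0). Between the times, 1 split reached 38 genes in *A. officinalis* (highest other 6). In *A. kiusianus* the real count between the times was 0 (edgeR, 1719 at an unadjusted p under 0.05, 170 by DESeq2), which any split reaches, so that the 10 of 10 says nothing about chance. The highest other split called 157 genes, which points to a structure of the samples. For the 2 sets of controls, 1 split reached 11595 (highest other 0).

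Genes named for the difference had these log2 values, *A. kiusianus* minus *A. officinalis*. At 24 hpi LOC109837305 stood at 14.38, LOC109830209 at 7.44, LOC109851211 at -19.83 and LOC109820463 at -15.62. Without *A. kiusianus* control library 1 LOC109851211 was at -6.07 (adjusted p = 0.0312) and LOC109820463 at -4.21 (adjusted p = 0.0103). At 48 hpi LOC109829694 stood at 12.84, LOC109849020 at 11.2, LOC109851211 at -17.69 and LOC109842870 at -16.19, and LOC109851211 at -3.88 without that library (adjusted p = 0.0921). Where a group had no count the fitted value depends on the prior count and is no bound on the fold.

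The first pattern is the presence of transcripts typical of *A. officinalis* in the *A. kiusianus* controls, with the 63 genes at a median of 17.8% of their *A. officinalis* level in control 2. *A. officinalis* RNA mixed into control 2 is argued against by exon coverage, with 46.4% of exons covered in full (95% bootstrap interval 36.9 to 54.7%). Exons of equal length and count reached 60.6% in *A. officinalis* and 51% in *A. kiusianus*. These values were not corrected for coverage in the library at large. Other genes of control 2 reached 62.8% against a matched 65.8% in *A. kiusianus*, so part of the gap may come from the library. Those of controls 1 and 3 lay above theirs, at 66.8% against 63.5% and 68.4% against 64.7%. In control 3 the exon coverage set as the test beforehand did not decide (42.9%, 31.6 to 52.7%). Its interval held both matched values, 43.9% in *A. officinalis* and 37.5% in *A. kiusianus*. The mixture is argued against there only by a test with limits set after the counts were seen. The test took genes with at least 10 CPM in every *A. officinalis* library. Of 7944 where the lower quartile of the share, 3.31%, would bring at least 20 counts, 5 had no count. At the median share 7 of 9141 had no count. In control 1 there was 1 such gene at the lower quartile and 3 at the median share, where 3 was the limit, so that the answer depends on the share taken and a mixture there cannot be told apart from the other explanations. Still open are *A. kiusianus* genes active without the fungus and shut off after inoculation, and material of another genotype in the controls. The shut-off predicts a median log2 ratio of control 2 to control 3 within those of random gene lists (-0.3 to 0.68). The ratio was 1.54 (quartiles over genes 1.25 to 1.76), which goes against it. Exon coverage in control 2 did not, since its interval held the matched *A. kiusianus* value. For another genotype, 11 genes read in the *A. kiusianus* controls alone gave a ratio of 0.57 (-0.31 to 1.34). This lay below those quartiles, with an interval that reached them.

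The second pattern is 1 count repeated over neighbouring genes of chromosome 8 in *A. kiusianus* control library 1. Transcription of these genes is argued against by 4 genes whose exon counts all equal 255783 exactly. Alignments with gaps that span whole genes, counted on each exon inside the gap, are a candidate explanation: all 17 protein-coding genes of the stretch had a smallest exon count within 1% of that number. The stretch is flanked by 10 pseudogenes. No biological explanation beyond transcription was tested.

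The third pattern is the place of *A. officinalis* 24 hpi library 3 near the controls. On a scale from the controls (0) to 48 hpi (1) it stood at 0.29, and the other libraries of its group at 0.95 and 0.9. A swap with control 1 or 2 is argued against, since neither stood above -0.06 on genes and a scale chosen without it and without library 3, which stood at 0.25 there. A swap with control 3 cannot be told apart from the labels as given, since control 3 stood at 0.32 and library 3 at 0.3 on such a scale, and the split that exchanges them called 3410 genes against the real 2531. A stem with less fungal growth or a slower response predicts a place above all the controls. On the first scale library 3 was above them, at 0.29 against at most 0.23, but the genes of that scale were chosen with control 3. On the scale chosen without both, library 3 at 0.3 was not above control 3 at 0.32. The positions thus do not decide, and this explanation stays open. A single uninoculated stem under another label stays open too. On the first scale 0.29 exceeded the highest control, 0.23, by less than the controls differ among themselves.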

How the results depend on the processing

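The neighbour subtraction, the largest count per exon cluster, the subtraction of an *A. officinalis* share and leaving out *A. kiusianus* controls 1 and 2, alone or with *A. officinalis* 24 hpi library 3, were chosen only after the data were seen. Of 279 counts of genes compared over the 9 comparisons, 207 were within 1.5 times the reported one and 72 moved. The cause was not tested unless given.

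DESeq2 called 4187 genes at 24 hpi in *A. officinalis*, 677 between its times, 170 between those of *A. kiusianus* and 4268 for the difference at 24 hpi. Between the *A. kiusianus* times, where edgeR called 0 (1719 at an unadjusted p under 0.05), coding segments gave 6 and no low-count filter 5. Fitting only the libraries of the species or groups compared, which leaves fewer samples for the spread, gave 738 and 2475 at 24 and 48 hpi in *A. officinalis*, 0 and 3 between the times of *A. officinalis* and *A. kiusianus*, and 1092 for the difference at 24 hpi. It also lowered the share of higher genes to 23.3% at 24 hpi in *A. officinalis* and raised it to 38.4% and 40.7% in *A. kiusianus*. The replicate block gave 1227 (30.8% higher) and 1618 at 24 hpi in *A. officinalis* and *A. kiusianus*, 14 between the times of *A. officinalis* and 1472 for the difference at 24 hpi. The share subtraction left 24 between the *A. officinalis* times.

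Without *A. kiusianus* controls 1 and 2, thus with 1 control assumed to vary like the other groups, the counts were 1048 and 1139 in *A. kiusianus*, 20 and 12 between the times of *A. officinalis* and *A. kiusianus*, 7547 between controls, and 1211 and 1697 for the differences. With *A. officinalis* 24 hpi library 3 out as well, they were 7072 at 24 hpi in *A. officinalis*, 1396 and 1476 in *A. kiusianus*, 648 and 44 between the times, and 4487 for the difference at 24 hpi.

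Leaving out 1 library at a time gave 897 to 6779 and 2481 to 6538 genes in *A. officinalis*, 1290 to 3310 and 1510 to 3695 in *A. kiusianus*, 8 to 713 and 0 to 39 between the times, 9502 to 12838 between controls, and 1323 to 6456 and 2252 to 5554 for the differences. The highest came without *A. officinalis* 24 hpi library 3, except the 39, without *A. kiusianus* 48 hpi library 2.

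Of 2736 values of named genes without 1 library, 2509 kept direction and side of the threshold, 205 lost the call, 19 gained it and 3 reversed. The losses were 39 of 152 without *A. kiusianus* controls 1 and 2, 16 of 152 with *A. officinalis* 24 hpi library 3 out as well, 25 of 152 with the block, 24 of 142 in that fit to fewer libraries, 12 of 152 with the share subtracted, 7 with the neighbour subtraction, 2 without the filter and 1 with exon clusters. The 3 were the 48 hpi difference of LOC109840277, at -0.08 and not past the threshold, which ranged from -0.36 to 0.15 and was 0.07 without *A. officinalis* control 1, 0.15 without *A. kiusianus* control 1 and 0.001 without its 48 hpi library 3. LOC109827318 reversed under the share subtraction, from -2.13 to 2.27 at 24 hpi and from -2.78 to 1.61 at 48 hpi, with adjusted p of 0.895 and 0.867. Coding segments, DESeq2 and the 1 CPM filter gave no value for some named genes. The 37 gene lists were not run.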

Other observations

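The counts of neighbouring pairs were planned before their results were seen, and the genes of the first paragraph were chosen after their values were seen.

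LOC109851004 on chromosome 1 (14082384 to 14096876) had no count in the *A. officinalis* controls and 68 ± 11.8 CPM in those of *A. kiusianus*, at least 2290-fold higher (adjusted p = 5.92e-06). LOC109833936 on chromosome 3 (42138203 to 42142597) rose in *A. kiusianus* from 109 ± 23 CPM in the controls to 2230 ± 422 CPM at 48 hpi (log2 fold change 4.35, SE 0.38, adjusted p = 1.34e-05). In *A. kiusianus* 11 genes had at least 2 CPM in each control and at most 0.2 CPM in each of the 6 inoculated libraries, and none had the reverse. Of these, 4 had controls within 3-fold of each other and 9 had a mean of at least 2 CPM in the *A. officinalis* controls. In *A. officinalis* the numbers were 1 and 0.

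A hypothesis that neighbouring genes change together was tested after the smallest exon count of the neighbours had been subtracted. Among 23437 adjacent pairs of tested genes, 203 pairs had calls in the same direction in *A. officinalis* at 24 hpi, 659 at 48 hpi, 252 in *A. kiusianus* at 24 hpi and 280 at 48 hpi. In 10000 random orders of the genes the highest numbers were 169, 531, 206 and 220 (permutation p = 1e-04 in each, the smallest that 10000 orders can give). Pairs called in opposite directions numbered 120, 452, 76 and 120, against means of 122.6, 457, 67 and 108.8. The longest run held 7 genes on chromosome 8 (5292627 to 5373961), LOC109820741 to LOC109822113, lower in *A. kiusianus* with a median log2 fold change of -3.53 at 24 hpi and -3.09 at 48 hpi. The counts may reflect shared regulation of neighbours, tandem gene copies or counts left from alignments with gaps, which these pairs do not separate.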
